A study of Homo sapiens with 139 samples.

How the data were processed

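RNA of milk fat globules, the lipid droplets that leave the milk-secreting cell wrapped in its membrane and a little cytoplasm, was measured on Illumina expression arrays. The 139 arrays came from 5 lactating women, numbered as replicates 2 to 6, over 4 labelled days. On days 1 to 3 the labels give 8 clock times, 3 h apart, and on day 4 they give 4 clock times (2, 8, 14 and 20 h). There were 40 arrays on day 1, 39 on day 2, 40 on day 3 and 20 on day 4, because replicate 4 lacks the sample of 2 h on day 2. Each day also carries a tag of its own in the labels, GH0 on day 1 and GH1 to GH3 on days 2 to 4. The labels do not say what the tag stands for, so a difference between days is also a difference between tags.

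Per the labels' protocols, total RNA was extracted with Trizol and amplified into biotin-labelled cRNA with an Illumina kit. Per the file headers, the deposited tables hold an average signal intensity for each probe and array, once without normalization and once after cubic spline normalization, and a detection p-value beside each intensity. The array software, its version and its background step are not stated. The authors' value table held the same numbers as the cubic spline table, with a largest difference of 0 over 3083576 values, so both count as 1 alternative. That table is on a linear scale and is not centred, and its array medians lay between 87.2 and 87.2. The signal column of 1 array carried another day and tag in its name than the same array's other columns, and those other columns settled which array it was. For 35 samples the description names another day or time than the title, and the titles were used. The bead number and bead standard error columns were not used.

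Gene names came from the platform annotation, updated through the gene identifier. Of 22184 probes, 19715 had 1 gene symbol, 0 had several and 2469 were unnamed here. The symbols of 19695 probes were looked up by gene identifier. XIST and Y-linked genes (53 probes) were left out of every step. Falls of an HLA class II gene that some people lack entirely and of C4B, whose copy number differs between people, are counted but not described.

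The signals without normalization were processed with limma 3.58.1 in R 4.3.3 and read with data.table (version 1.17.8); sample titles were read with jsonlite 2.0.0. Its function neqc corrected the background by normexp with a negative control spread inferred from the detection p-values, normalized by quantiles, added an offset of 16 and took log2. A gene was tested if a probe of it had a detection p under 0.01 in at least 20 arrays, which left 8873 genes. A gene was represented by its detected probe with the highest mean over all arrays, and 645 genes had more than 1 detected probe. Among the largest rises and falls named per day contrast, 6 pairs of a gene and a contrast had more than 1 detected probe. The probes went opposite ways in 0 of them. Genes named for other reasons were not part of this count. A gene counted as detected in an array when any of its probes had a detection p under 0.01. Median raw signals per array ran from 59.0 to 137, and the arrays detected 5970 to 9325 genes, with a median of 8087. Arrays give no counts, so the number of women and arrays limits the precision, and log2 changes of genes near background are compressed. Where a gene was detected on no array of the lower day, its change is given as at least a fold. That fold is the mean of the higher day against, per array, the higher of the lowest signal among detected probes and the gene's own. Where that fold is under 1, as for MB on day 2, no fold is given.

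The woman was the unit of replication. For the day contrasts, each woman gave 1 mean per day over the 4 clock times that all days share, which left out the time that replicate 4 lacks from all the days of that woman. So 19 arrays stand behind each day. The 20 values entered 1 limma fit with the day and a block for the woman, followed by a moderated two-sided test, Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. The pairing comes from the labels, which name the same woman on every day. Deviations from the group means correlated at a median of 0.624 between arrays of the same woman on different days and at -0.18 between women. Taking out the group means by itself pushes the correlation between women below 0. No 2 arrays held identical values, and the highest correlation between 2 arrays was 0.996.

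For the time of day, a 24 h cosine was fitted to each woman with a mean for each of the woman's days. The 5 pairs of coefficients entered limma, whose moderated F-test asked whether their mean differed from 0. The amplitude is the distance from the mean to the peak on the log2 scale, and the peak hour is the clock hour of the fitted maximum. The difference in rhythm between days 3 and 1 used the same test on each woman's difference in coefficients. Trends over time assume that each labelled day runs from 11AM to 8AM of the next morning and that the days follow each other, since no dates are given. Values after ± are standard errors (SE) of limma's fit unless SD is written, which is the spread over the 5 women.

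Before the data were examined, 31 gene lists were fixed, along with the comparisons, the rule for naming genes and the alternatives, save those given below as added later. Cytosolic ribosomal proteins and nuclear-encoded oxidative phosphorylation genes were taken by symbol pattern, the others by hand. Lists with at least 3 measured members were tested with limma's camera at its preset inter-gene correlation of 0.01, with the estimated correlation as the alternative, and list members called rhythmic were counted with Fisher's exact test against all other genes tested. The genes named are, per day contrast, the 12 largest rises and 12 largest falls among called genes that moved the same way in all 5 women. For the rhythm they are the 15 largest amplitudes and each measured clock gene, and for the difference in rhythm the 5 largest. From each list up to 4 members are named, the called ones with the largest change. CCND1, CSN2 and LALBA, and the rhythms of MT2A and NR3C1, were named outside this rule, after their values were seen.

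The tests were also run on simulated data with the same 8873 genes and arrays. In the day 4 against day 1 test, 81 of 100 genes with a simulated log2 change of 0.5 and 99 of 100 with a change of 1 were called, beside 9 of 8673 unchanged genes. In the rhythm test, 95 of 100 genes with an amplitude of 0.2 were called, beside 9 of 8573 genes without a rhythm. In the test of the difference in rhythm, 91 of 100 genes with a difference of 0.6 were called, beside 8 of 8773 others. The simulated noise was drawn independently for each gene, with no drift and no effect shared between genes. These rates of false calls therefore need not hold for the real data. Each simulated change or rhythm was also the same in every woman. Where real ones differ between women, fewer may be called.

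The alternatives were the cubic spline table, quantile normalization without background correction, median scaling, no filter and a filter of 70 arrays on dim probes, every detected probe, leaving out each replicate, no block for the woman, array weights, all 8 clock times, single arrays with a random block, single days, and a linear trend within a day. Covariates for array quality, cubic trends and leaving out the array with the fewest detected probes were added after the data were seen. Also unplanned were the linear trend in the test of the difference in rhythm and every alternative for the rhythm counts of the lists. The same holds for list shifts by day without background correction or with median scaling. The share of variance by woman, day and clock time came from sequential sums of squares per gene. Figures were drawn with matplotlib 3.10.9.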

Results

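The data are the RNA levels of milk fat globules from 5 lactating women, sampled around the clock over 4 labelled days on 139 arrays. Globules carry cytoplasm of the secreting mammary cell, so their RNA has been used as a sample of that cell. A median of 8087 genes was detected per array (range 5970 to 9325), 10333 genes in at least 1 array and 5283 in every array, out of 16540 named on the array. The probes of CSN3 and LALBA, which encode kappa-casein and alpha-lactalbumin, had day 1 means of 15.27 and 15.21 on the log2 scale, near its top. The woman accounted for a median of 31.5% of a gene's variance, the day for 4.30% and the clock time for 5.34%, with 51.2% left over. By their degrees of freedom alone, these 3 factors would take 2.90%, 2.17% and 5.07%. The mean number of detected genes per woman was 7946 ± 116 (SD, n = 5) on day 1 and 8261 ± 129 on day 4. It was higher on day 4 in 5 of 5 women, by 315 ± 217 (SD), with an exact two-sided permutation p of 0.0625, the smallest that 5 women allow.

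The title describes globule RNA followed over 4 days, and the first question is which transcripts moved between days at the same clock times. Days 2, 3 and 4 were each set against day 1, so these 3 contrasts share the day 1 arrays and are not independent of each other. Genes named as risen or fallen in these contrasts without a count of women moved the same way in all 5.

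Day 2 was set against day 1 first. TYMS, which makes thymidylate for DNA, rose by 1.42 ± 0.23 on the log2 scale (2.67-fold, adjusted p = 0.00729, n = 5 women), and DTL, a ubiquitin ligase subunit of replication control, by 1.22 ± 0.22 (2.33-fold, adjusted p = 0.0117). TOP2A (2.23-fold), GINS2 (2.04-fold), CDK1 (2.02-fold, with a second probe at 0.28 on the log2 scale), NUSAP1 (2.02-fold), NCAPG (1.87-fold), PCLAF (1.81-fold), PTTG1 (1.71-fold), CDCA5 (1.68-fold), STMN1 (1.56-fold) and the tubulin gene TUBB4B (1.53-fold) also rose, with adjusted p between 0.00551 and 0.0422. All but PCLAF, STMN1 and TUBB4B were detected on 1 or 2 of 19 day 1 arrays, so these folds start from signals near background. S100A8, a subunit of the antimicrobial protein calprotectin, fell by 1.55 ± 0.32 (adjusted p = 0.0208), and its partner S100A9 by 0.87 ± 0.20 (adjusted p = 0.0343). The defensin gene DEFB1 fell by 1.15 ± 0.22, the T cell inhibitor gene VTCN1 by 1.12 ± 0.13 and the antigen-loading gene HLA-DMB by 0.81 ± 0.14. FAXDC2, MUC20, KCNAB1, XAF1, SAT1 and YPEL3 fell by between 1.56- and 1.89-fold, with adjusted p between 0.00197 and 0.0221. MB fell as well (adjusted p = 0.0237), and was detected on 11 of 19 arrays on day 1 and on 0 of 19 on day 2. Outside these, the glutathione synthesis gene GCLM rose by 0.45 ± 0.10. Falls outside the largest were IFIT1 of the interferon response by 0.51 ± 0.07, the protease genes CTSD by 0.43 ± 0.10 and CTSS by 0.38 ± 0.07, CD74 by 0.46 ± 0.11, and ZBTB16 by 0.51 ± 0.12 (lower in 4 of 5 women).

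In all, 157 of 8873 genes were called on day 2, of which 54 rose and 103 fell (153 in the same direction in 5 women, and 1785 at an unadjusted p under the threshold). Of 22 cell cycle genes measured, 4 rose over all genes tested and 14 adjusted over the list alone, with a median log2 change of 0.36. The list's camera adjusted p was 3.0e-11, and 0.219 with an estimated correlation. Lower as lists were the macrophage and monocyte markers (median -0.30, 1 of 11 fell, 7 adjusted over the list alone), the neutrophil markers (-0.64, 2 of 4, 3 over the list alone), the inflammatory and NF-kB targets (-0.26, 1 of 13, 6) and the interferon response (-0.25, 2 of 15, 6). Also lower were the glucocorticoid-responsive genes (-0.19, 1 of 15, 1 over the list alone), the myoepithelial markers (-0.25, 1 of 4, 2), the involution genes (-0.12, 3 of 13, 5) and the tight junction genes (-0.24, 0 of 8, 3). The endoplasmic reticulum stress and chaperone list was higher (median 0.17, 0 of 22 rose over all genes and 6 adjusted over the list alone). The camera adjusted p of these 9 lists lay between 0.000124 and 0.0270, and none held with an estimated correlation (adjusted p = 0.219 to 0.283). The day 2 count was 1051 with all 8 clock times, 911 with array weights, 717 with single arrays and a random block, 370 without the array with the fewest detected probes, 70 with the detected-probe covariate and 0 with no replicate block (370 at an unadjusted p under the threshold in limma). It also moved with the women included: without replicate 6 the fit called 0 genes (1093 at an unadjusted p under the threshold), without replicate 4 it called 14, without replicate 2 it called 36, without replicate 3 it called 66 and without replicate 5 it called 300. CDK1, PCLAF, PTTG1, CDCA5, STMN1, S100A8, S100A9, MUC20, MB, SAT1, YPEL3, GCLM, CTSD and CD74 were also not called without replicate 2, 3 or 4, and the tight junction list not without replicate 3 or 6. DEFB1, HLA-DMB and CTSS lost the call without replicate 2 or 4, TOP2A and NUSAP1 without 3 or 4, ZBTB16 without 3, 4 or 5, NCAPG without 3, and TUBB4B and KCNAB1 without 4.

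On day 3, TYMS rose by 3.57 ± 0.23 on the log2 scale against day 1 (11.9-fold, adjusted p = 3.5e-08, n = 5 women), TOP2A by 3.14 ± 0.22 (8.82-fold), the mitotic kinase gene CDK1 by 3.06 ± 0.23 (8.34-fold, with a second probe at 1.51) and the spindle gene NUSAP1 by 3.05 ± 0.20 (8.28-fold). DTL, NCAPG, GINS2, PTTG1, CEP55, PRC1, CCNB2 and CDCA5 rose by between 5.13- and 7.06-fold, with adjusted p of 2.2e-07 or lower. All 12 were detected on 1 to 3 of 19 day 1 arrays, so these folds start from signals near background. S100A8 fell 4.00-fold (adjusted p = 0.000380), the lysosomal glycoprotein gene CD68 by 1.28 ± 0.20 and the acute phase inhibitor SERPINA3 by 1.08 ± 0.14. FAXDC2, VTCN1, DEFB1, HLA-DMB, TYROBP and MUC20 fell by between 1.87- and 2.66-fold, with adjusted p of 0.00768 or lower. IGSF6, MB and C1QTNF5 fell as well (adjusted p of 0.000981 or lower), from detection on 12, 11 and 9 of 19 day 1 arrays to 1 of 19 each on day 3.

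Of 8873 genes, 1839 were called on day 3, of which 790 rose and 1049 fell (1564 in the same direction in 5 women). Of the 22 cell cycle genes 21 rose, also adjusted over the list alone, and their median change was 1.52, or 1.41 with the 3 members not detected on day 1 set at their lower bound (camera adjusted p = 9.1e-32, and adjusted p = 0.102 with an estimated correlation). The macrophage and monocyte markers were lower (median -0.41, 7 of 11 fell over all genes and over the list alone). Among them CD74, the chaperone of class II molecules, fell by 0.70 ± 0.11, and the receptor chain FCER1G by 0.78 ± 0.22 (lower in 4 of 5 women). The inflammatory list was lower by a median of -0.47 (8 of 13 fell, 9 adjusted over the list alone), with the chemokine CCL2 down by 0.72 ± 0.23 in 4 of 5 women and the NF-kB inhibitor NFKBIA by 0.49 ± 0.12. The glucocorticoid-responsive list was lower by a median of -0.32 (5 of 15 fell, 6 adjusted over the list alone), with TSC22D3 down by 0.63 ± 0.10. The chaperone list was higher (median 0.16, 8 of 22 rose over all genes and over the list alone), led by the disulfide isomerases PDIA6 (0.60 ± 0.14) and PDIA4 (0.44 ± 0.10) and by CRELD2 (0.45 ± 0.09). The nuclear oxidative phosphorylation list was higher by a median of 0.09 (7 of 59 rose, 4 adjusted over the list alone). Lower too were the neutrophil markers (median -0.65, 3 of 4 fell, 3 adjusted over the list alone), the myoepithelial markers (-0.25, 2 of 4, 2), the interferon response (-0.32, 8 of 15 and 1 rose, 9 and 1) and the involution genes (-0.13, 5 of 13 and 1 rose, 5 and 1). The camera adjusted p of these 9 lists other than the cell cycle lay between 0.00186 and 0.0462, and none held with an estimated correlation (adjusted p = 0.285 to 0.316). Array weights gave 3287 genes on day 3, all 8 clock times 3265, and no replicate block 249, of which 169 rose and 80 fell. Without replicate 2 the day 3 fit called 1056 genes, without replicate 4 it called 1005 and without replicate 6 it called 960. CCL2 and FCER1G lost the call without replicate 2, 3 or 4, NFKBIA without 3, the neutrophil list without 2, 3, 4 or 6, the involution list without 3, 4 or 6, the myoepithelial list without 3 or 6 and the interferon list without 4 or 5.

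The 12 genes with the largest rises on day 4 were detected on all 19 day 4 arrays used. TYMS rose by 4.55 ± 0.23 on the log2 scale against day 1 (23.4-fold, adjusted p = 1.3e-10, n = 5 women). NUSAP1 rose by 4.37 ± 0.20 (20.7-fold), TOP2A by 4.32 ± 0.22, CDK1 by 4.22 ± 0.23 (18.6-fold, with a second probe at 2.61), the securin gene PTTG1 by 4.02 ± 0.18 (16.2-fold) and the condensin gene NCAPG by 3.93 ± 0.18 (15.3-fold). CEP55, CCNB2, PRC1 and DTL rose by between 11.2- and 13.8-fold, and GINS2 by 3.45 ± 0.16. The mitotic kinase gene PBK was detected on 0 of 19 day 1 arrays and was at least 4.39-fold higher on day 4 (adjusted p = 2.2e-10). The other 11 were detected on 1 to 3 of 19 day 1 arrays, where signals near background compress a log2 change. S100A8 fell by 1.96 ± 0.32 (3.88-fold, adjusted p = 0.000286), SERPINA3 by 1.53 ± 0.14 (2.89-fold, adjusted p = 3.7e-07), FAXDC2 by 1.51 ± 0.12, CD68 by 1.40 ± 0.20, CD74 by 1.09 ± 0.11 and HLA-DMB by 1.04 ± 0.14. STAC2, VTCN1, DACT1, CXCL17, PIP and PIK3IP1 fell by between 1.95- and 2.05-fold, with adjusted p of 0.000106 or lower.

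Against day 1, 2064 of 8873 genes were called on day 4, of which 875 rose and 1189 fell (1554 in the same direction in 5 women). Changes over 2-fold were mostly rises: 132 genes rose and 11 fell by more. Of the 22 cell cycle genes 21 rose, also adjusted over the list alone, with a median change of 2.36, or 2.17 with the 3 members not detected on day 1 at their lower bound (camera adjusted p = 1.1e-37, and adjusted p = 0.0563 with an estimated correlation). The mean over the list was higher than on day 1 in 5 of 5 women, by 0.47 ± 0.17 (SD) on day 2, 1.63 ± 0.30 on day 3 and 2.36 ± 0.41 on day 4. The member that was not called was the cyclin D1 gene CCND1, at 0.03 ± 0.10. The macrophage and monocyte markers were lower by a median of -0.31 (5 of 11 fell over all genes and over the list alone). Among them HLA-DRA fell by 0.65 ± 0.06 and CD14 by 0.31 ± 0.09 (lower in 4 of 5 women). The inflammatory list was lower by a median of -0.32 (6 of 13 fell and 1 rose, 7 and 1 adjusted over the list alone), with complement C3 down by 0.77 ± 0.14 and SOD2 down by 0.62 ± 0.13 while the chemokine CXCL2 rose by 0.48 ± 0.16 in 4 of 5 women. The nuclear oxidative phosphorylation list was higher by a median of 0.10 (10 of 59 rose and 1 fell, 7 and 1 adjusted over the list alone), led by the complex I gene NDUFA9 (0.30 ± 0.06), NDUFB6 (0.28 ± 0.07) and the ATP synthase gene ATP5F1A (0.28 ± 0.06). The camera adjusted p of these 3 lists was 0.00811, 0.0265 and 0.000724, and with an estimated correlation adjusted p = 0.506, 0.523 and 0.506.

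**Figure D1:**
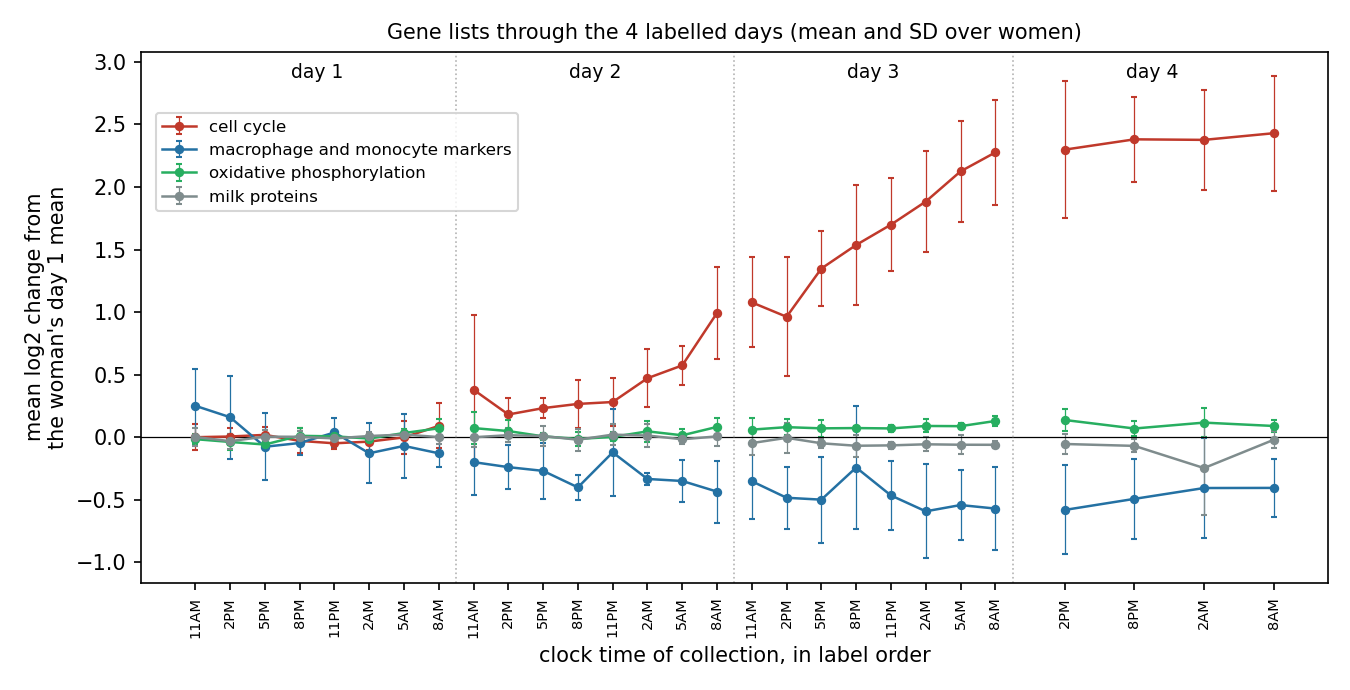
Mean log2 change of 4 gene lists from each woman's day 1 mean (vertical axis) at each clock time in label order (horizontal axis); points are means and bars SDs over the women (5, or 4 at 2AM of day 2). The cell cycle list stood at 0.99 at 8AM of day 2, at 2.28 at 8AM of day 3 and at 2.43 at 8AM of day 4, while the milk proteins lay between -0.25 and 0.02 throughout.

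Single members of other lists moved on day 4 without a call for their list. The immediate early genes FOS and EGR1 rose by 0.92 ± 0.19 and 0.72 ± 0.17 (adjusted p = 0.00196 and 0.00503), the quinone reductase gene NQO1 by 0.62 ± 0.13, the antiviral gene OAS3 by 0.73 ± 0.10 and the desaturase gene FADS1 by 0.54 ± 0.11 (higher in 4 of 5 women). IGFBP2, a binding protein of insulin-like growth factors, rose by 0.57 ± 0.10, and TIMELESS, of the clock list, by 1.13 ± 0.11. CRY2 of the same list fell by 0.52 ± 0.09, the glucocorticoid-responsive TSC22D3 by 0.69 ± 0.10 and ZBTB16 by 0.56 ± 0.12, the interferon-induced GBP2 by 0.60 ± 0.09, and the lysosomal proteases CTSB by 0.68 ± 0.10 and CTSS by 0.55 ± 0.07. Among luminal epithelial genes KIT fell by 0.46 ± 0.08, the oestrogen receptor gene ESR1 by 0.41 ± 0.07 and GATA3 by 0.40 ± 0.09. Both measured lymphocyte markers fell, IL7R by 0.50 ± 0.09 and CD79B by 0.26 ± 0.07. Of 12 milk protein genes only the folate receptor gene FOLR1 fell, by 0.39 ± 0.08, also over the list alone. The beta-casein gene CSN2 was at -0.02 ± 0.05 and LALBA at 0.00 ± 0.05, near the top of the signal scale, where an array compresses changes.

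The medians of the lists without a call on day 4 were between -0.43 and 0.11. Lowest were the neutrophil (-0.43), myoepithelial (-0.29), interferon (-0.26), clock (-0.19), glucocorticoid-responsive (-0.19), adipocyte and stromal (-0.18), involution (-0.17) and luminal epithelial markers (-0.14). Close to 0 were the genes of amino acid transport (-0.09), prolactin, growth hormone and IGF signalling (-0.08), triglyceride synthesis (-0.08), tight junctions (-0.08), the globule membrane (-0.03), milk proteins (-0.03), immediate early genes (-0.02), ribosomal proteins (-0.01) and cholesterol synthesis (0.01). Above 0 were oxidative stress genes (0.03), fatty acid synthesis (0.05), hypoxia and glycolysis (0.05), heat shock genes (0.06), lactose synthesis (0.08), chaperones (0.08) and mineral transport (0.11). The mean differed in sign from the median for cholesterol synthesis, immediate early genes and ribosomal proteins. The 2 measured keratinocyte markers were not called, and 0 red cell markers were measured. With the number of detected probes per woman and day in the fit, 507 genes were called on day 4, of which 331 rose and 176 fell, 465 of them among the 2064; S100A8, C3, SOD2, CD14, CXCL2, CRY2, ZBTB16, KIT, GATA3, FOLR1, IL7R, CD79B and ATP5F1A were then not called, and neither were the macrophage and inflammatory lists. With no replicate block 337 genes were called, of which 242 rose and 95 fell. Without replicate 4 the day 4 fit called 1101 genes, without replicate 6 it called 1224 and without replicate 2 it called 1339. CD14 and CD79B lost the call without replicate 4 or 6, CXCL2 without 2, 5 or 6 and the inflammatory list without 3 or 4.

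Day 4 was also set against day 2, a contrast that leaves the day 1 arrays out of the difference. NUSAP1 rose by 3.36 ± 0.20 on the log2 scale (10.3-fold, adjusted p = 2.6e-09, n = 5 women), PTTG1 by 3.24 ± 0.18 (9.46-fold), CDK1 by 3.20 ± 0.23 (9.18-fold, with a second probe at 2.33), TOP2A by 3.17 ± 0.22 (8.98-fold), the cyclin gene CCNB2 by 3.14 ± 0.16 (8.83-fold) and TYMS by 3.13 ± 0.23 (8.74-fold). PBK, NCAPG, CEP55, PRC1, CCNA2 and KIF20A rose by between 6.40- and 8.27-fold, with adjusted p of 5.8e-09 or lower. Of the 19 day 2 arrays, KIF20A was detected on 1, PBK on 2 and TYMS, the most often detected of these 12 genes, on 14. So these folds also start in part from signals near background. FOS rose by 0.95 ± 0.19 (adjusted p = 0.00322), the phosphatase gene DUSP1 by 0.81 ± 0.21, OAS3 by 0.75 ± 0.10 and EGR1 by 0.72 ± 0.17. SERPINA3 fell by 0.96 ± 0.14 (adjusted p = 0.000157), the prolactin-inducible gene PIP by 0.66 ± 0.14, CD74 by 0.62 ± 0.11 (second probe -0.91), the adaptor gene SKAP1 by 0.60 ± 0.11 and HLA-DRA by 0.41 ± 0.06. DACT1, FAXDC2, STAC2, GALNT4, ALDH2 and C4BPA fell by between 1.42- and 1.53-fold. Of 8873 genes, 500 were called, of which 342 rose and 158 fell (483 in the same direction in 5 women), and changes over 2-fold were rises for 113 genes and falls for 0. Of 22 cell cycle genes 20 rose, 21 adjusted over the list alone, with a median change of 2.03 (camera adjusted p = 4.2e-55). This was the only list call in the 4 day contrasts that held with an estimated correlation (adjusted p = 0.0129). The oxidative stress and metallothionein list (median 0.26, 0 of 13 called, camera adjusted p = 0.0451) and the nuclear oxidative phosphorylation list (median 0.06, 0 of 59 called, adjusted p = 0.00111) were higher, with adjusted p = 0.559 and 0.685 with an estimated correlation. Array weights gave 979 genes, of which 482 rose and 497 fell, and no replicate block 181, of which 178 rose and 3 fell. Without replicate 4 this contrast called 272 genes, and EGR1, DUSP1, DACT1 and FAXDC2 were not among them. EGR1 also lost the call without replicate 6, DUSP1 and the oxidative stress list without 5 or 6, STAC2 without 2 and FAXDC2 without 3.

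The clock times of the samples pose the second question, which transcripts varied with the time of day. The largest swing was that of HSD11B2, which encodes the enzyme that inactivates cortisol. Its amplitude was 1.25 ± 0.09 on the log2 scale (5.66-fold from trough to peak, adjusted p = 1.8e-06, n = 5 women), with a peak at 13.5 h ± 0.639 (SD). Clock transcripts followed in order of the day: NR1D2 peaked at 8.75 h (amplitude 0.99 ± 0.05, 3.94-fold), TEF at 11.8 h (0.76 ± 0.06), DBP at 12.9 h (0.55 ± 0.04), PER2 at 13.5 h (0.96 ± 0.07, 3.79-fold), CRY2 at 14.1 h (0.72 ± 0.04), BHLHE40 at 14.3 h (0.46 ± 0.03) and CRY1 at 17.6 h (0.56 ± 0.04). Their transcriptional activators peaked at night, BMAL1 at 21.1 h (0.17 ± 0.05), CLOCK at 22.2 h (0.31 ± 0.08) and NPAS2 at 0.402 h (0.31 ± 0.03). Of the glucocorticoid-responsive list, 4 members with wide swings peaked around midday, FKBP5 at 12.6 h (0.80 ± 0.06, 3.02-fold), ZBTB16 at 12.8 h (0.70 ± 0.06), SGK1 at 10.7 h (0.67 ± 0.04) and KLF9 at 11.4 h (0.46 ± 0.03). Other wide swings were those of FMO5, LMO3, TFCP2L1, SOX8, RASL12, NRCAM and NPFFR2, with amplitudes between 0.62 and 0.78 and peaks between 12.4 and 15.9 h.

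A 24 h rhythm was called for 3199 of 8873 genes (36.1%, and 4228 at an unadjusted p under the threshold), and 3026 of them peaked within 6 h of the mean peak in 5 of 5 women. Most swings were small, with a median amplitude of 0.14 (1.21-fold from trough to peak), 238 genes over 1.5-fold and 31 over 2-fold. Peaks fell in every 3 h of the day, most often between 3 and 6 h (550 genes) and between 12 and 15 h (513 genes). Of 16 clock genes 14 were rhythmic, and 15 adjusted over the list alone (Fisher's exact test against all other genes, adjusted p = 0.000183). Fisher's test takes genes as independent, which members of a list are not. Its p-values, here and for the lists below, therefore only describe these samples. Of the others, CSNK1D (amplitude 0.05 ± 0.03) was not called either way, and TIMELESS (0.07 ± 0.02) only over the list alone. CSNK1E (0.24 ± 0.03), HLF (0.13 ± 0.02), NFIL3 (0.18 ± 0.03) and RORA (0.10 ± 0.02) were called.

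**Figure D2:**
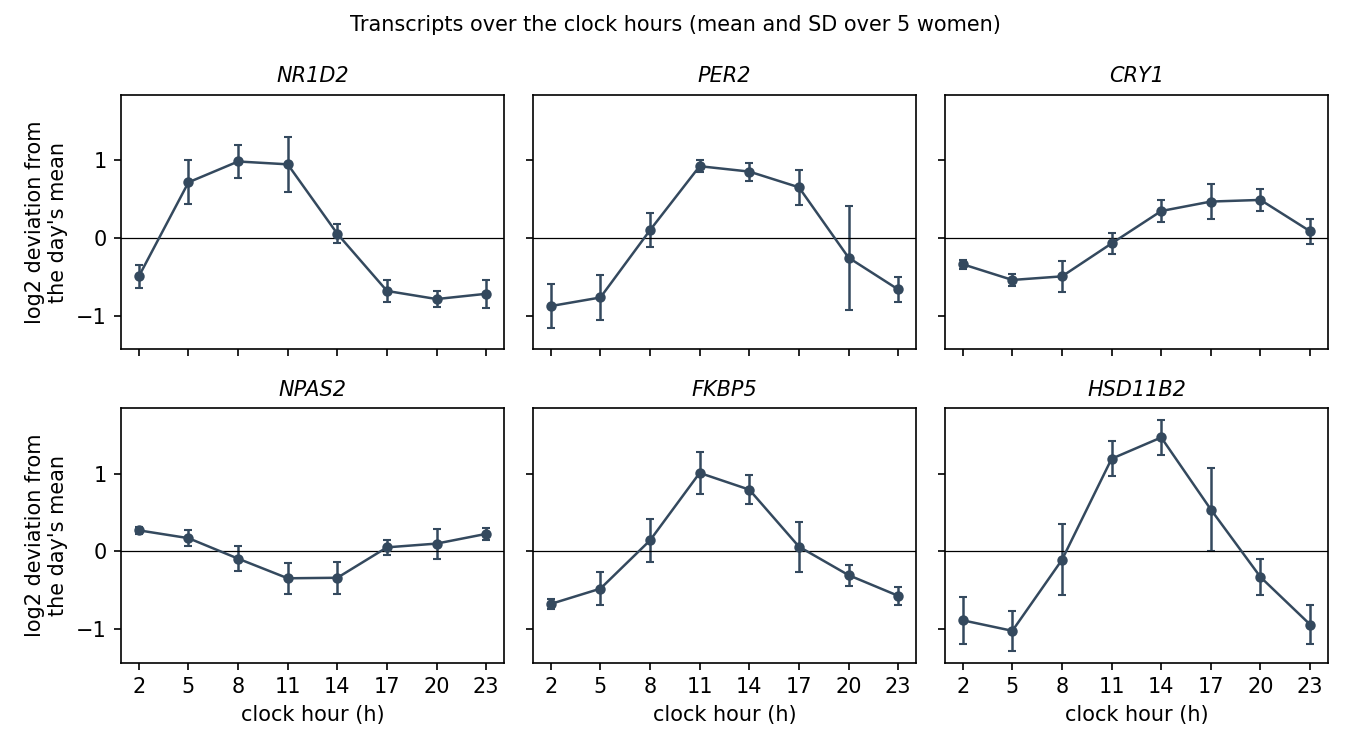
Log2 deviation from the woman's mean of the day (vertical axis) by clock hour (horizontal axis, h) for 6 transcripts; points are means and bars SDs over 5 women, days pooled. The fitted peaks were at 8.75 h for NR1D2, 13.5 h for PER2, 17.6 h for CRY1, 0.402 h for NPAS2, 12.6 h for FKBP5 and 13.5 h for HSD11B2.

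Rhythmic genes were more frequent than among other genes in 4 further lists and less frequent in 3. Of 22 chaperone and endoplasmic reticulum stress genes 19 were rhythmic (20 adjusted over the list alone, Fisher adjusted p = 1.1e-05) with a mean peak at 21.2 h, led by HSPA5, the BiP chaperone gene, with an amplitude of 0.46 ± 0.05 and a peak at 19.8 h, by HERPUD1 (0.32 ± 0.07 at 16.7 h) and by HYOU1 (0.30 ± 0.05 at 22.0 h). Of 13 amino acid transporter genes 11 were rhythmic (11 over the list alone, adjusted p = 0.00217) with a mean peak at 17.9 h, among them SLC36A1 (0.40 ± 0.04 at 14.1 h), SLC7A5 (0.30 ± 0.04 at 21.3 h) and SLC7A2 (0.28 ± 0.03 at 17.4 h). Of 15 glucocorticoid-responsive genes 12 were rhythmic (14 over the list alone, adjusted p = 0.00259) with a mean peak at 12.3 h, though MT2A peaked at 21.2 h and NR3C1 at 3.91 h. Of 22 cell cycle genes 20 were rhythmic (21 over the list alone, adjusted p = 3.2e-06) with a mean peak at 4.75 h, such as TOP2A (0.49 ± 0.04 at 4.45 h), TYMS (0.42 ± 0.03 at 4.35 h) and CCNB2 (0.41 ± 0.04 at 5.12 h). These genes also climbed from day to day, and with a linear trend within each day 3 of the 20 were called, TOP2A, TYMS and CCNB2 not among them. Fewer members than among other genes were rhythmic for ribosomal proteins (4 of 59, 1 over the list alone, adjusted p = 3.2e-06), nuclear oxidative phosphorylation (4 of 59, 0 over the list alone, adjusted p = 3.2e-06) and milk proteins (0 of 12 either way, adjusted p = 0.0201). The milk protein result was lost with quantile normalization without background correction (adjusted p = 0.123) and with median scaling (0.208), and some of these probes sit near the top of the signal scale. The amplitude of CSN2 was 0.02 ± 0.02 and that of LALBA 0.01 ± 0.02. Elsewhere the calcium pump gene ATP2B2 swung with an amplitude of 0.59 ± 0.03 (peak at 14.0 h), KIT with 0.48 ± 0.06 (13.7 h), the keratin gene KRT7 with 0.43 ± 0.04 (16.2 h) and ACACB, of fatty acid oxidation control, with 0.32 ± 0.03 (14.5 h).

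**Figure D3:**
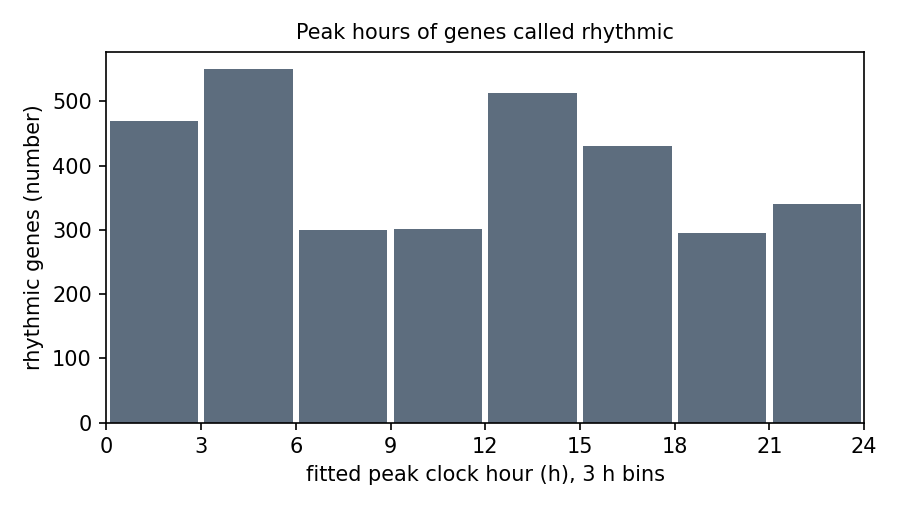
Number of genes called rhythmic (vertical axis) by fitted peak clock hour in bins of 3 h (horizontal axis, h). The bins from 3 to 6 h and from 12 to 15 h hold the most genes, 550 and 513, and the bin from 18 to 21 h the fewest, 295. Drift within a labelled day was not removed from these fits.

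With a linear trend within each labelled day in the fit, 835 genes were called rhythmic, 810 of them among the 3199, at a median SE 1.31 times as large. Of the 14 clock genes 10 stayed called in that fit, and BMAL1 (amplitude 0.17), CLOCK (0.32), HLF (0.13) and RORA (0.12) did not, at amplitudes close to those without the trend. The cell cycle, oxidative phosphorylation and milk protein lists were then no longer set apart by their share of rhythmic genes, while the luminal epithelial (adjusted p = 0.000615) and interferon lists (0.0393) then were. Without replicate 2 the rhythm test called 2111 genes. BMAL1 lost the call without replicate 2, 4 or 6 and RORA without 2, 3, 4 or 6, and TIMELESS gained it without 3.

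The last comparison asks whether a rhythm differed between days 3 and 1, both sampled at 8 clock times. Its size is the amplitude of the difference between the 2 fitted curves, not a difference of amplitudes. The 5 largest were those of the mitosis genes CCNB2 (0.93 ± 0.11, adjusted p = 0.00149, n = 5 women), DLGAP5 (0.92 ± 0.09), KIF20A (0.92 ± 0.10), PBK (0.92 ± 0.08, adjusted p = 0.000146) and NUSAP1 (0.90 ± 0.13). The amplitude of CCNB2 was 0.18 on day 1 and 0.92 on day 3, and its day 3 peak was at 4.04 h. Of the 19 day 1 arrays behind the day contrasts, CCNB2 and NUSAP1 were detected on 1 and PBK on 0. Signals near background compress a log2 change, so a day 1 rhythm of such genes could go unseen. Of the 22 cell cycle genes 16 were among the 293 genes called (3.30% of 8873, and 1841 at an unadjusted p under the threshold), and 0 of the 16 clock genes were. The difference for NR1D2 was 0.06 ± 0.11 (adjusted p = 0.928) and that for PER2 0.25 ± 0.09 (adjusted p = 0.223). With a linear trend within each day 0 genes were called (605 at an unadjusted p under the threshold). Without replicate 4 the test called 90 genes, without replicate 3 it called 100, without replicate 6 it called 125 and without replicate 2 it called 174.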

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

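The tests of leukocyte markers, of the clock genes under a trend, of array covariates and of cubic trends, and the trend in the test of the difference in rhythm, were chosen after the results they concern were seen.

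The rise of the cell cycle genes on day 4 was weighed against 3 technical explanations. The measured neutrophil, macrophage and lymphocyte markers, many of which the mammary epithelium also expresses, had a median log2 change of -0.32 (15 of 17 below 0). A 95% bootstrap interval over the 17 genes ran from -0.57 to -0.14. It takes the genes as independent and does not measure the spread over women. Over the women, the mean change was -0.44 ± 0.29 (SD, lower in 5 of 5) for the macrophage and monocyte list. For the neutrophil list it was -0.71 ± 0.64 (SD, lower in 4 of 5). The lower median argues against a general rise of leukocyte RNA only as far as these markers stand for leukocytes. Of the dimmer markers SPI1 (-0.31) and CD79B (-0.26) were called. TYROBP (-0.57), FCER1G (-0.44), AQP9 (-0.32), VSIG4 (-0.14), ITGAX (-0.08), AIF1 (0.01) and MRC1 (0.11) were not. Only 4 neutrophil and 2 lymphocyte markers were measured, so an addition of leukocyte RNA is not excluded. Without any normalization the median change of the cell cycle list was 1.79, beside 1.72 with quantile normalization of the same signals, and with the number of detected probes as a covariate it was 2.17 beside 2.36, which argues against normalization and brighter arrays as the whole cause. Day, tag and order of collection move together in this design, so their effects cannot be told apart, and no array batch is given. Proliferation of the secreting cells is a candidate explanation that these data leave as a hypothesis.

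The number of genes with a 24 h rhythm was weighed against drift and array quality. With the number of detected probes and the raw signal as covariates 2860 of 3199 genes stayed called at a median of 97.6% of their size, and with a cubic trend over all hours in place of the day means 2488 did at 92.5%, which argues against array quality and, except for the cell cycle list (10 of 20 stayed called, median amplitude 0.24 to 0.09), against a steady change over the 4 days. With a linear trend within each labelled day 810 stayed called, which is what had been set down for drift as the cause; yet the median amplitude of these 3199 genes was 0.12 beside 0.14, with a median SE 1.31 times as large, and 3152 kept their peak within 6 h. Since a trend over a day overlaps with a 24 h sine, drift within a day and a rhythm cannot be told apart for most of these genes, the comparison of sizes was added after the count was seen, and every trend assumes that a labelled day starts at 11AM. For the clock list 10 of 14 genes stayed called with the trend, with a median amplitude of 0.35 beside 0.39, which argues against drift as the cause of their rhythm.

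The rhythm of 293 genes differed between days 3 and 1, most of all for CCNB2 (0.93), DLGAP5 (0.92), KIF20A (0.92), PBK (0.92) and NUSAP1 (0.90), by a test of the difference itself. Over the 16 cell cycle genes among them the median amplitude of the difference between the 2 fitted curves was 0.64. With a linear trend within each day it was 0.23 and limma called 0 of the 16, and with a cubic trend over all hours removed it was 0.21 and limma called 0, as a steady climb through day 3 would give. A climb that goes on through day 3 is therefore a candidate explanation of these differences, and a changed 24 h rhythm of cell cycle genes was not shown. CCNB2, PBK and NUSAP1 were also near background on day 1, where a rhythm could go unseen.

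For 8 of 190 pairs of a named gene and a contrast, the value of 1 woman stood apart, where chance gives about 1 in 20. The gap to the nearest other woman, as a share of the range over 5 women, was 0.794 for TOP2A and 0.741 for SAT1 on day 2, 0.801 for MB, 0.763 for MUC20 and 0.805 for TSC22D3 on day 3, and 0.765 for STAC2 on day 4. For the amplitude of the rhythm it was 0.724 for CRY2 and 0.739 for CLOCK. The number of detected genes stood apart in 1 array in 5 of 28 groups of day and clock time, with shares of 0.863 at 8PM and 0.727 at 8AM of day 2, 0.722 at 8PM and 0.738 at 8AM of day 3, and 0.713 at 2PM of day 4. The array with the fewest detected genes (5970) was among them. Of 804 probes without a gene name, 132 were called between days 4 and 1, of which 58 rose and 74 fell.

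Exchanging day labels within women gives 16 splits per day contrast, of which 1, the real one, called as many genes; 16 splits are too few for a share under 0.05. The real count and the highest of the other splits were 157 and 0 for day 2 against day 1, 1839 and 292 for day 3, 2064 and 1704 for day 4, 500 and 0 for day 4 against day 2, and 293 and 0 for the difference in rhythm. The split with 1704 calls exchanged the labels of 1 woman, and the next highest called 1 gene. For the rhythm, 1 of 100 sets of clock hours shifted per woman, the real one, called as many genes (3199, and 2225 at most in the others). So it is unlikely that the women shared their peak hours by chance. A drift within the day that all women shared would pass this test too.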

How the results depend on the processing

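Covariates for detected probes, cubic trends, the trend in the test of the difference in rhythm and leaving out the array with the fewest detected probes were chosen after the data were seen. The alternatives for the rhythm counts of the lists, and those without background correction or with median scaling for list shifts by day, were not planned either. No named day change or list shift that was called changed its sign under any alternative run, while the peak of TIMELESS, whose rhythm was not called, moved from 4.66 to 15.1 h with a linear trend within a day. The cubic spline table, quantile normalization without background correction, median scaling and every detected probe kept each count of called genes within 1.5 times. The filter on dim probes moved only the difference in rhythm (293 genes), to 129 without it and to 187 at 70 arrays. Of the alternatives for named genes, 2098 day results kept their side of the threshold and 273 lost it. For rhythms 888 kept it, 49 lost it and 5 gained it, for differences in rhythm 57 kept it and 10 lost it, and for lists 241 kept it and 56 lost it.

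Leaving out 1 replicate gave 0 to 300 genes on day 2 against day 1, 960 to 2227 on day 3, 1101 to 2636 on day 4, 272 to 483 for day 4 against day 2, 2111 to 2727 for the rhythm and 90 to 301 for the difference in rhythm, with 23 to 33 list calls by day beside 27. The 0 came without replicate 6, where limma called 1093 genes at an unadjusted p under the threshold. Fewer women leave fewer degrees of freedom, and the cause of the spread was not tested further. With no replicate block for the woman the day contrasts called 0 (370 at an unadjusted p under the threshold), 249, 337 and 181 genes in the same order, since differences between women then enter the error. With single arrays as the unit, the rhythm test called 4565 genes with a replicate block for woman and day and 2634 with no replicate block, beside 3199 by woman. Of the genes called without a block on days 3 and 4 against day 1, most rose (169 of 249 and 242 of 337), where with the block most fell.

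Array weights gave 911 genes on day 2 against day 1, 3287 on day 3 and 979 for day 4 against day 2. All 8 clock times of days 1 to 3 gave 1051 on day 2 and 3265 on day 3, and single arrays with a random block 717 on day 2. With the number of detected probes as a covariate 70 genes were called on day 2 and 507 on day 4, and without the array with the fewest detected probes 370 on day 2. For these the cause was not tested. The rhythm was called for 1018 genes on day 1 alone, for 2477 on day 2 alone, for 1323 on day 3 alone and for 835 with a linear trend within a day. The difference in rhythm was called for 0 genes by limma with a linear trend (605 at an unadjusted p under the threshold) or with a cubic trend removed (883). With an estimated correlation between genes 1 list call by day was left of 27. A detection p under 0.05 in place of 0.01 moved the median number of detected genes from 8087 to 10108.

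A filter that drops arrays with few detected genes removed no array, a block for the array chip could not be made because the chip is not named, and the authors' value table equals the cubic spline table, so these were not run. Signals close to background limit the size of changes, as for the cell cycle genes on day 1, and signals near the top of the scale limit those of the caseins.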

Other observations

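Both hypotheses below were tested after the pattern had been seen in the same data. For the test on members detected on day 1 the prediction was set down before its result, but it uses the same women and days.

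Most glucocorticoid-responsive genes shared a peak around midday. FKBP5, ZBTB16, SGK1 and KLF9 peaked between 10.7 and 12.8 h, and the mean peak of the 12 rhythmic members was at 12.3 h. MT2A, which metals also induce, peaked at 21.2 h (amplitude 0.22 ± 0.06), and the glucocorticoid receptor gene NR3C1 at 3.91 h (0.18 ± 0.04). With a linear trend within a day 7 of the 12 stayed called. MT2A and NR3C1 were not called rhythmic without replicate 2 or 6 or with a linear trend within a day, and MT2A not without replicate 3. The peaks lay closer together than those of random sets of 12 rhythmic genes: their concentration, from 0 for spread to 1 for identical, was 0.668 beside a median of 0.245 and a 95th percentile of 0.496 over 10000 sets, with a share of 0.00340 as high. Rhythmic members of some other lists were closer still, such as the involution (0.757, mean peak at 12.5 h), chaperone (0.722 at 21.2 h) and amino acid transport genes (0.764 at 17.9 h). The clock (0.340) and fatty acid synthesis lists (0.115) were among those more spread. So close peaks are not particular to the glucocorticoid-responsive list. A daily rhythm of glucocorticoid action on the secreting cell is a candidate explanation, and no hormone level is among these data. None of the 12 is on the clock list, though PER1, which was not measured, is on both lists, and some of these genes may follow the clock directly.

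The order in which replication and mitosis genes moved was also compared. Lists of 36 genes of the S phase and 43 of the G2 and M phases, of which 9 and 7 are also on the cell cycle list, were compared by the share of their day 4 change reached on day 2. It was 24.1% ± 7.82 (SD, n = 5 women) for the S phase and 14.1% ± 6.79 for the G2 and M phases, higher for the S phase in 5 of 5 women (SD of the difference 1.57 points, exact two-sided permutation p = 0.0625, the smallest that 5 women allow). On day 3 the shares were 74.5% and 60.3%. The log2 changes on day 2 were 0.31 ± 0.12 (SD) for the S phase and 0.27 ± 0.13 for the G2 and M phases. They were 0.95 and 1.12 on day 3, and 1.29 and 1.85 on day 4. So the lower share of the G2 and M phases went with a larger day 4 change, while the day 2 changes were close. Dim probes near background could give such a difference in shares. Among the 21 and 16 members detected on at least 10 of the day 1 arrays used, it was 9.73 ± 5.33 points (SD), again in 5 of 5 women. An ordered entry of cells into the cycle may account for this, as a hypothesis. A larger day 4 rise of the G2 and M phase genes would give the difference in shares as well.

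Among the 2549 genes called in any day contrast 52.1% were rhythmic (1329 genes), and among the other 6324 genes 29.6% (1870). These rhythms were fitted without a trend, so a climb or fall through the days can enter the 24 h cosine. Of the 20 rhythmic cell cycle genes, 3 stayed called with a linear trend within a day. Whether day changes and daily rhythms go together was not tested. The woman accounted for 73.0% of the first principal component. The second component held 13.7% of the variance, of which the day accounted for 44.7% and the woman for 35.6%. The mean number of detected genes by clock time lay between 7803 at 23 h and 8178 at 14 h.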
